A study of Mus musculus with 95 samples.

How the data were processed

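RNA was measured in nucleus accumbens punches of mice that carry a tagged ribosomal protein, Rpl10a fused to a fluorescent protein, under the control of Aldh1l1, an astrocyte gene. Per the labels' protocols, translating ribosome affinity purification of the tagged ribosomes gave the IP library of a mouse, and an aliquot kept from before the purification gave its input library. Libraries were made with a Takara SMART-Seq PLUS kit. The series holds 95 libraries of 49 mice, of which 46 have both libraries and 3 have the input only. Each mouse belongs to 1 of 3 treatments (dependent, non-dependent or naive), 1 sex and 1 of 6 batches.

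The values used were gene counts as the authors deposited them, in 1 table with a column per library. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39 and STAR 2.7.10b were used with the GRCm38 genome. The counting program, its annotation and its use of strand were not given in the sources used here. Reads of overlapping genes, of antisense partners and of close paralogs, among them the H2 genes and the globin pair Hba-a1 and Hba-a2, therefore could not be told apart with certainty. The table lists 55471 features, of which 55144 matched a symbol of the reference annotation (GENCODE mouse release M21), and the 327 others held 0.0192% of all counts. At least 1 count was present for 40308 features.

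Total counts ran from 14314236 to 27146790 in the 46 IP libraries and from 12803108 to 23948193 in the 49 input libraries. Mitochondrially encoded transcripts took 0.486% to 2.17% of the counts of an IP library and 6.85% to 17.9% of those of an input library. The levels of 4 Y-linked genes matched the sex label of all 95 libraries, while those of Xist overlapped (at least 0.952 CPM in females, at most 1.25 CPM in males). The IP and input of a mouse are paired by the labels, and the data were checked for it. Means of each treatment by sex by fraction group were subtracted, but batch means were not, so both values below include what libraries of a batch share. The 2 libraries of a mouse then had a median correlation of 0.643 across 9159 genes, against 0.472 for libraries of different mice in the same batch. That correlation was over 0.1 in 45 of 46 mice and -0.333 in the remaining mouse, and 31 IP libraries correlated best with their own input. Principal component 1 of the 1000 most variable genes followed batch (R2 0.874 in IP and 0.888 in input). No 2 libraries were duplicates.

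Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (TMM normalization, filterByExpr with its minimum count of 10 and minimum total of 15, robust dispersion). P-values were adjusted by the Benjamini-Hochberg method and called at or under 0.05. Treatments were compared separately in IP and in input, in 1 fit per fraction with a mean for each treatment by sex and a term for batch. A treatment difference is the mean of the female and the male difference. These fits held batches I, J, K and L: 16 dependent, 15 naive and 13 non-dependent IP libraries, and 16, 16 and 15 input libraries. Batches C and G hold 1 dependent female each and give no treatment difference once batch is a term. Batch I holds no naive mouse and batch L no non-dependent mouse, so the difference between non-dependent and naive mice rests on batches J and K and on the dependent mice that link the others. IP and input were compared over the 46 mice with both libraries, with the mouse as a block. Whether a treatment difference was larger in one fraction was tested in the 44 such mice of batches I to L, with the mouse as a block and a batch term for the IP. In these paired fits the dispersion was estimated inside glmQLFit from the top 5% of genes by abundance, a setting chosen after the data were seen because a separate dispersion estimate was slow. The separate estimate was run as an added alternative. Standard errors of log2 fold changes came from the F statistic. CPM values, which are counts scaled by library size, are given as mean and SD over the fitted libraries of a group without batch adjustment, so they can differ from the fitted log2 fold changes.

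Gene lists, 41 in all, were fixed beforehand for cell types, astrocyte reactivity, immune signalling, stress responses, metabolism and the clock, and 777 of their 779 members matched 1 gene each. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01), again with an estimated correlation, and with fry. List calls are at an adjusted p at or under 0.05 over the lists of a comparison. Members are counted as higher or lower by the test over all genes and, where stated, adjusted over the list alone. The genes named are, per comparison, up to 8 higher and 8 lower genes with the smallest adjusted p, a mean of at least 1 CPM and an established symbol, up to 4 members with the smallest p of a described list, the 6 genes with the smallest p where fewer than 6 pass, and Xist, Ddx3y, Uty, Kdm5d, Eif2s3y, Rpl10a, Aldh1l1 and Gfap. The lists, the tests, the alternatives and this naming rule were set before the data were examined, apart from the dispersion setting of the paired fits.

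The alternatives were DESeq2 1.42.0, its size factors in edgeR, limma voom with quality weights, no count filter, a stricter filter (1 CPM in 10 libraries), no batch term, batches J and K only, a composition covariate, an additive sex term, only mice with an IP library, no mouse block, leaving out each library or batch in turn, and for lists the other tests. The fits without a batch term also hold the dependent females of batches C and G, so they change the samples as well as the model. The composition covariate is the mean log2 CPM of astrocyte markers minus that of neuron and oligodendrocyte markers. Each model was tested on simulated counts with 200 changed genes. All genes were drawn with a dispersion of 0.05 and without batch or mouse effects. Recovery is therefore likely lower for genes that vary more among mice, such as the MHC genes in dependent mice. In the IP comparison of dependent with naive mice, 59.7% of simulated 1.5-fold, 89.6% of 2-fold and 90.9% of 4-fold changes were recovered (18288 genes). For the difference between sexes in that comparison the shares were 10.4%, 53.7% and 89.4% (18263 genes). In the paired fit by treatment for dependent and naive mice they were 25.4%, 77.6% and 98.5% (4419 genes). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.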

Results

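The study asked how astrocytes of the nucleus accumbens respond to alcohol dependence, by comparing the RNA on astrocyte ribosomes (IP) with RNA of the whole tissue (input) in mice. Dependent mice went through 5 rounds of CIE, a chronic intermittent ethanol exposure, in a protocol with voluntary drinking (CIE-2BC). Non-dependent mice had the drinking part alone (2BC), and naive mice received no ethanol. The IP libraries come from 18 dependent mice (10 female, 8 male), 15 naive mice (8 female, 7 male) and 13 non-dependent mice (8 female, 5 male). The input libraries come from 18 dependent (10 female, 8 male), 16 naive (8 female, 8 male) and 15 non-dependent mice (8 female, 7 male). An IP library held between 14314236 and 27146790 counts and an input library between 12803108 and 23948193.

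The first comparison asked what the purification enriched. Astrocyte transcripts were enriched in IP (median log2 fold change of their markers 3.12), while transcripts of neurons, oligodendrocytes, microglia and endothelial cells were depleted. Slc1a3, the astrocyte glutamate transporter GLAST (ENSMUSG00000005360, chromosome 15), averaged 3037 ± 318 CPM in IP and 381 ± 46.6 CPM in input (SD, 46 mice), a log2 fold change of 3.17 ± 0.03 (SE, adjusted p = 7.59e-66). Aldh1l1, whose regulatory sequence drives the ribosome tag, had 146 ± 40.2 CPM in IP and 19.5 ± 6.52 CPM in input (log2 fold change 3.09 ± 0.05, adjusted p = 3.33e-53). Snap25, a synaptic vesicle fusion protein of neurons, had 620 ± 147 CPM in IP and 1732 ± 352 CPM in input (log2 fold change -1.32 ± 0.03, adjusted p = 1.45e-42). Slc1a3 and Aldh1l1 were higher in the IP of 46 of 46 mice, and Snap25 was higher in 0 of 46.

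All 22 astrocyte markers were higher in IP (median log2 fold change 3.12), among them Gfap (3.43), the connexin gene Gja1 (3.25) and the glial transcription factor Sox9 (3.11). Of the markers of other cells, 15 of 15 neuron markers (median -1.30), 16 of 16 medium spiny neuron markers (median -1.13) and 13 of 13 endothelial markers (median -1.07) were lower. The spiny neuron peptide genes Penk and Tac1 had log2 fold changes of -1.35 ± 0.04 and -1.45 ± 0.03. Of 13 oligodendrocyte markers, 11 were lower, 1 was higher and 1 did not pass (median -1.33). All 18 microglia markers were lower (median -1.03, adjusted p = 0.0503 with an estimated correlation), among them the complement gene C1qb at -1.30 ± 0.05. The 13 mitochondrially encoded transcripts were all lower (median -3.58), with mt-Nd1 at 569 ± 169 CPM in IP and 8239 ± 2286 CPM in input. Adjusted over the list alone, the same numbers of members passed in these 7 lists. Rpl10a, the gene of the tagged protein, differed little (173 ± 35.1 and 175 ± 69.4 CPM, log2 fold change 0.23 ± 0.05, adjusted p = 1.47e-05) and was higher in the IP of 27 of 46 mice.

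Lists of astrocyte functions followed the markers, although some members, such as Slc1a2 and Gja1, are also in the marker list. Higher in IP were 12 of 13 potassium, water and gap junction genes (1 lower, median 2.93), 16 of 20 fatty acid and lipoprotein genes (4 lower, median 2.25; Apoe 3.05 ± 0.04) and 12 of 16 genes of glutamate and GABA handling (4 lower, median 1.77; Slc1a2 2.91 ± 0.04). Of 20 oxidative stress response genes, 17 were higher, 1 was lower and 2 did not pass (median 1.70). Interferon response genes were also enriched: 25 of 35 were higher, 3 lower and 7 did not pass (median 1.01, adjusted p = 0.0487 with an estimated correlation), with Ifit3 at 2.56 ± 0.05. Of 16 MHC class I and antigen processing genes, 11 were higher and 2 lower (median 0.87, adjusted p = 0.115 with an estimated correlation), with H2-K1 at 1.57 ± 0.05. Adjusted over the list alone, these 6 lists had the same counts. In all, 17078 of 21743 tested genes differed, 7301 higher and 9777 lower in IP.

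**Figure D1:**
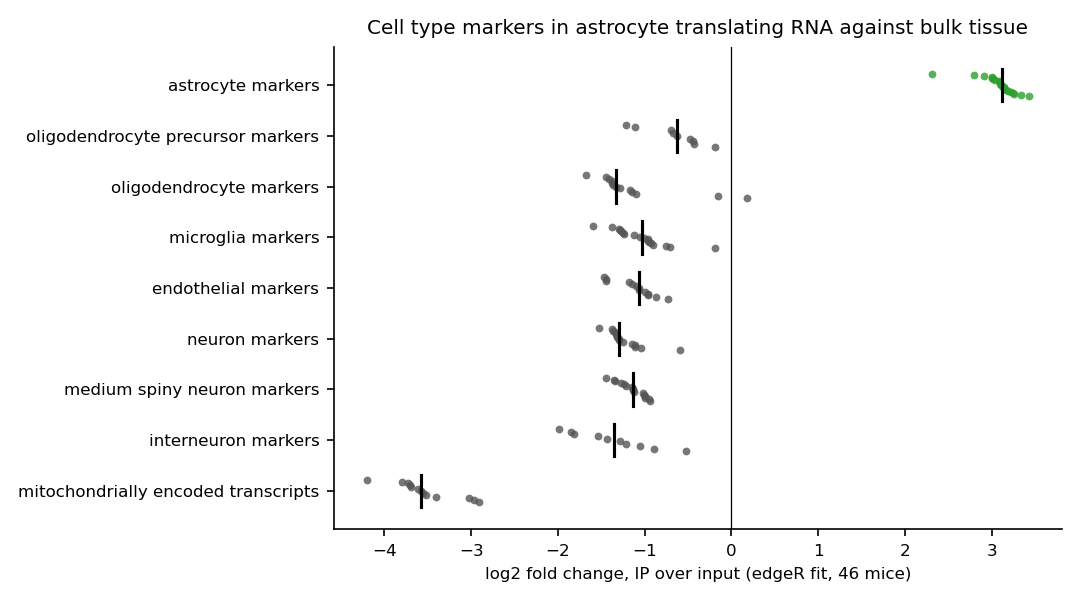
Log2 fold change of IP over input for each cell type marker (points), grouped by marker list, over 46 mice. Astrocyte markers lie near 3, and markers of neurons, oligodendrocytes, microglia and endothelial cells lie mostly below 0.

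The comparison of dependent with non-dependent mice in IP asked what dependence adds to drinking alone. Genes of antigen presentation, of the interferon response and of protein folding in the endoplasmic reticulum were higher in the astrocyte ribosomes of dependent mice. Psmb8, a catalytic subunit of the immunoproteasome (ENSMUSG00000024338, chromosome 17), rose from 6.17 ± 2.26 CPM in 13 non-dependent to 44.8 ± 51.2 CPM in 16 dependent libraries (SD; log2 fold change 2.81 ± 0.44 SE, adjusted p = 0.000337). H2-Ab1, an MHC class II chain, had 0.877 ± 0.638 and 47.5 ± 69.2 CPM (log2 fold change 5.36 ± 0.75, adjusted p = 0.000103). Cebpb, a transcription factor of inflammatory and stress genes, had 14.4 ± 2.71 and 39.4 ± 20.01 CPM (log2 fold change 1.49 ± 0.17, adjusted p = 1.06e-06). The dependent mice varied widely: over all 18 of them, H2-D1 ranged from 80.8 to 1260 CPM and the class II invariant chain gene Cd74 from 0.986 to 301 CPM, against 38.2 to 159 and 0.171 to 2.99 CPM in non-dependent mice.

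Of 16 MHC class I and antigen processing genes, 15 rose and 1 did not pass (16 adjusted over the list alone, median log2 fold change 1.82), with H2-D1 at 1.92 ± 0.32 and H2-T23 at 2.64 ± 0.44. Of 9 MHC class II genes, 5 rose and 4 did not pass (7 adjusted over the list alone), with Cd74 at 5.45 ± 0.91 (adjusted p = 0.000706). Of 33 type I interferon response genes, 16 rose (26 adjusted over the list alone, median 1.20), among them Xaf1 (2.14 ± 0.32), Bst2 (3.22 ± 0.54) and Ifi27 (1.20 ± 0.22). Of 16 interferon-inducible GTPases and interferon gamma response genes, 12 rose (14 adjusted over the list alone, median 2.55), among them the transcription factor gene Irf1 (1.57 ± 0.29) and Igtp (3.14 ± 0.57). No member of these 4 lists fell. Of 15 complement genes, 6 rose and 9 did not pass (7 adjusted over the list alone), with C4b at 1.04 ± 0.19 and C1qc, also a microglia marker, at 0.83 ± 0.19. Of 11 A1-like reactive astrocyte genes, 6 rose (7 adjusted over the list alone, median 1.92), and of 21 JAK-STAT receptors and regulators 3 rose (4 adjusted over the list alone, median 0.05), among them Stat3 (0.43 ± 0.09) and the interferon receptor gene Ifnar2 (0.44 ± 0.09). These 7 lists kept their call with an estimated correlation. The A1-like list is not separate from the others. Its H2-D1, H2-T23 and Psmb8 are also MHC class I members, Gbp2 and Iigp1 are also interferon-inducible GTPases, and Serping1 is also a complement member.

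Of 20 unfolded protein and integrated stress response genes, 11 rose and 9 did not pass (adjusted over the list alone, 14 higher and 1 lower, median 0.42). Among them were Manf, a secreted protein of endoplasmic reticulum stress (104 ± 34.1 and 176 ± 53.5 CPM, 0.86 ± 0.12, adjusted p = 3.89e-05), and the chaperone genes Calr (0.83 ± 0.13) and Hspa5 (0.63 ± 0.12). Of 20 oxidative stress response genes, 8 rose and 12 did not pass (13 adjusted over the list alone, median 0.32), with the sulfiredoxin gene Srxn1 at 0.67 ± 0.10 and Mgst1, a microsomal glutathione transferase, at 0.54 ± 0.08. Of 24 cholesterol synthesis genes, 2 rose and 22 did not pass (5 adjusted over the list alone, median 0.17, adjusted p = 0.328 with an estimated correlation), with the sterol sensor gene Insig1 at 0.80 ± 0.15. Of 18 microglia markers, 4 rose and 14 did not pass (8 adjusted over the list alone, median 0.41, adjusted p = 0.328 with an estimated correlation). Of 16 medium spiny neuron markers, 1 fell and 15 did not pass (3 lower adjusted over the list alone, median -0.24, adjusted p = 0.179 with an estimated correlation). Of 22 astrocyte markers, none passed (median 0.05), and Gfap had a log2 fold change of 0.23 ± 0.17 (adjusted p = 0.693).

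In total 308 of 19979 tested genes differed, 219 higher and 89 lower in dependent mice, and 18 lists were called higher and 3 lower, of which 14 kept the call with an estimated correlation. Within batches I, J and K the difference of mean log2 CPM of the MHC class I list was 2.17 (7 against 7 mice), 1.63 (4 against 3) and 0.37 (2 against 3). The MHC class II list gave 3.06, 2.03 and -0.28, and the interferon list 1.47, 1.07 and 0.02. The unfolded protein list gave 0.58, 0.41 and 0.18, and Cebpb 1.74, 0.97 and 1.64. Microglia markers gave 0.40, 0.23 and -0.20 in the same batches. The dependent mice I02, I11, I05 and J05 had the highest MHC class I means. Their microglia marker means were 5.48, 4.15, 4.36 and 4.86 log2 CPM, against 3.63 in the non-dependent mice of batch I and 3.82 in those of batch J. In batches J and K alone edgeR called 0 genes (1720 at an unadjusted p under 0.05). In all 4 batches DESeq2 called 492 and limma voom 229, while the fit with a composition covariate called 253 (145 higher and 108 lower) and that with no count filter 684. The fit without a batch term, which also holds batches C and G, called 92 (75 higher and 17 lower). Cd74 and C1qc lost their call with limma voom, and C1qc, Hspa5 and Srxn1 without a batch term.

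**Figure D2:**
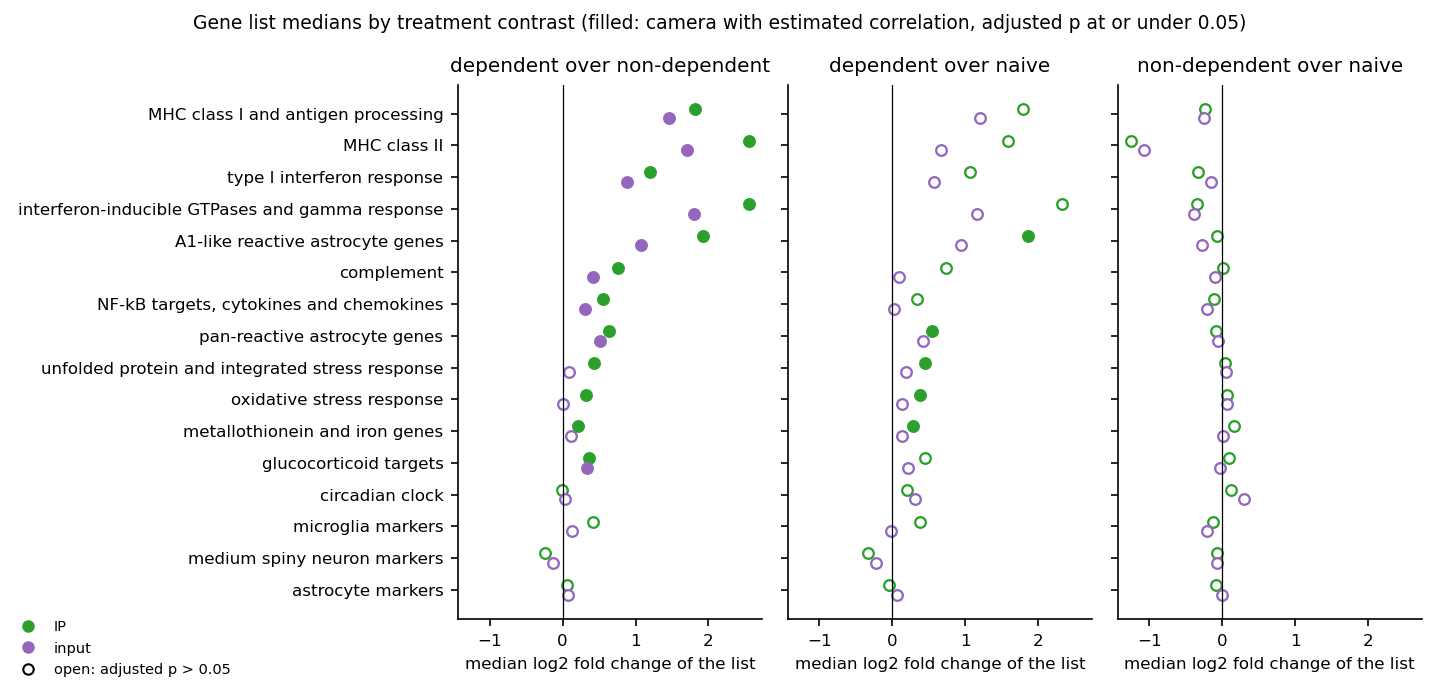
Median log2 fold change of the tested members of 16 gene lists in the 3 treatment comparisons, in IP (green) and input (purple). Filled points are lists called with an estimated correlation, which occur for dependent over non-dependent mice in both fractions and for 5 lists of the IP for dependent over naive mice.

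The comparison of dependent with naive mice in IP covers ethanol vapor and drinking together. Genes of the oxidative stress and unfolded protein responses and metallothionein and iron genes were higher in dependent mice, and Fabp7, Rgs4 and Gabbr2 were among the lower genes. Gstm1, a glutathione transferase (ENSMUSG00000058135, chromosome 3), rose from 3746 ± 405 CPM in 15 naive to 6012 ± 987 CPM in 16 dependent libraries (SD; log2 fold change 0.71 ± 0.07 SE, adjusted p = 7.76e-09), with 5024 ± 886 CPM in non-dependent libraries. Fabp7, the fatty acid binding protein of astrocytes and radial glia, fell from 470 ± 133 to 152 ± 53.8 CPM (log2 fold change -1.48 ± 0.14, adjusted p = 1.31e-09). Rgs4, a regulator of G protein signalling, fell from 103 ± 23.1 to 56.6 ± 12.7 CPM (log2 fold change -1.002 ± 0.11, adjusted p = 1.39e-07). Rgs4 was less abundant in IP than in input, where it fell as well, and a share of RNA from other cells was not tested.

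Of 20 oxidative stress response genes, 12 rose and 8 did not pass (12 adjusted over the list alone, median 0.38), among them Srxn1 (62.7 ± 11.3 and 146 ± 60.6 CPM, 0.87 ± 0.11), Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (0.71 ± 0.10), and Osgin1, a target of the redox factor Nrf2 (3.46 ± 0.46). Of 20 unfolded protein and integrated stress response genes, 12 rose and 8 did not pass (15 adjusted over the list alone, median 0.44), among them the chaperone genes Canx (0.43 ± 0.06) and Calr (0.82 ± 0.14), Manf (0.65 ± 0.12) and Xbp1, a transcription factor of that response (0.57 ± 0.11). Of 12 metallothionein and iron genes, 5 rose (7 adjusted over the list alone, median 0.28), with Mt1 at 0.91 ± 0.11, the ferritin gene Ftl1 at 0.54 ± 0.09 and the transferrin receptor gene Tfrc at 0.78 ± 0.14. Of 11 A1-like reactive astrocyte genes, 7 rose (7 adjusted over the list alone, median 1.86), among them H2-D1 (69.8 ± 20.9 and 379 ± 385 CPM, 1.86 ± 0.33), Gbp2 (2.85 ± 0.50) and the complement inhibitor gene Serping1 (2.17 ± 0.41). Of 12 pan-reactive astrocyte genes, 2 rose (5 adjusted over the list alone, median 0.54), the intermediate filament genes Vim (0.80 ± 0.12) and Gfap (322 ± 141 and 852 ± 540 CPM, 0.98 ± 0.18, adjusted p = 0.000517). No member of these 5 lists fell, and they kept their call with an estimated correlation. The A1-like list shares members with the MHC class I, interferon-inducible GTPase and complement lists, among them H2-D1, Gbp2 and Serping1.

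The remaining called lists did not keep it. Of 16 MHC class I and antigen processing genes, 12 rose and 4 did not pass (16 adjusted over the list alone, median 1.79, adjusted p = 0.051 with an estimated correlation). Of 33 type I interferon response genes, 13 rose (21 adjusted over the list alone, median 1.06, adjusted p = 0.0984 with an estimated correlation). Of 15 complement genes, 3 rose (3 adjusted over the list alone, median 0.74, adjusted p = 0.051 with an estimated correlation), with C4b at 1.03 ± 0.19. Of 15 glucocorticoid targets, 6 rose (8 adjusted over the list alone, median 0.45, adjusted p = 0.0572 with an estimated correlation), among them Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (1.11 ± 0.17). Of 29 NF-kB targets, cytokines and chemokines, 7 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.33, adjusted p = 0.0572 with an estimated correlation), among them the cytokine gene Il18, which fell by 0.52 ± 0.11 on the log2 scale. Of 16 genes of glutamate and GABA handling, 3 fell (4 adjusted over the list alone, median -0.08, adjusted p = 0.205 with an estimated correlation), among them the metabotropic glutamate receptor gene Grm3 (-0.52 ± 0.08). Of 16 medium spiny neuron markers, 3 fell and 13 did not pass (11 lower adjusted over the list alone, median -0.33, adjusted p = 0.18 with an estimated correlation), among them the adenosine receptor gene Adora2a (-0.56 ± 0.14). Of 13 oligodendrocyte markers, 1 fell and 12 did not pass (2 lower adjusted over the list alone, median -0.14, adjusted p = 0.213 with an estimated correlation). None of the 15 neuron markers passed (median -0.01, not called), nor did any of 18 microglia markers (0 adjusted over the list alone, median 0.37, adjusted p = 0.463 with an estimated correlation).

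Other named genes were Cebpb (10.2 ± 3.20 and 39.4 ± 20.01 CPM, 1.53 ± 0.18, adjusted p = 2.81e-07), the fatty acid desaturase gene Scd1 (1.07 ± 0.14), the GABA-B receptor gene Gabbr2 (248 ± 52.9 and 130 ± 31.8 CPM, -0.89 ± 0.11) and the alpha-globin gene Hba-a2 (16.5 ± 9.601 and 0.0820 ± 0.131 CPM, -7.36 ± 0.56). Fabp7, Gabbr2 and Hba-a2 also fell between naive and non-dependent mice. For such genes a strain variant shared by the non-naive mice cannot be told apart from ethanol. In total 933 of 19979 tested genes differed, 561 higher and 372 lower, and 17 lists were called higher and 6 lower. Within batches J, K and L (4 against 4, 2 against 4 and 3 against 7 mice) the difference of mean log2 CPM of the oxidative stress list was 0.47, 0.42 and 0.53. The unfolded protein list gave 0.44, 0.44 and 0.36, and the MHC class I list 1.97, 0.67 and 0.93. The metallothionein list gave 0.24, 0.28 and 0.33, the A1-like list 1.85, 0.76 and 0.85, and the pan-reactive list 0.85, 0.20 and 0.46. Medium spiny neuron markers gave -0.60, -0.12 and -0.20, Fabp7 -1.38, -1.60 and -1.55, and Rgs4 -1.02, -1.15 and -1.05. In batches J and K alone 235 genes passed, where Canx, Manf, Gfap and Il18 lost their call, and with no count filter 1447. With a composition covariate 475 were higher and 421 lower, and without a batch term Adora2a lost its call.

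**Figure D3:**
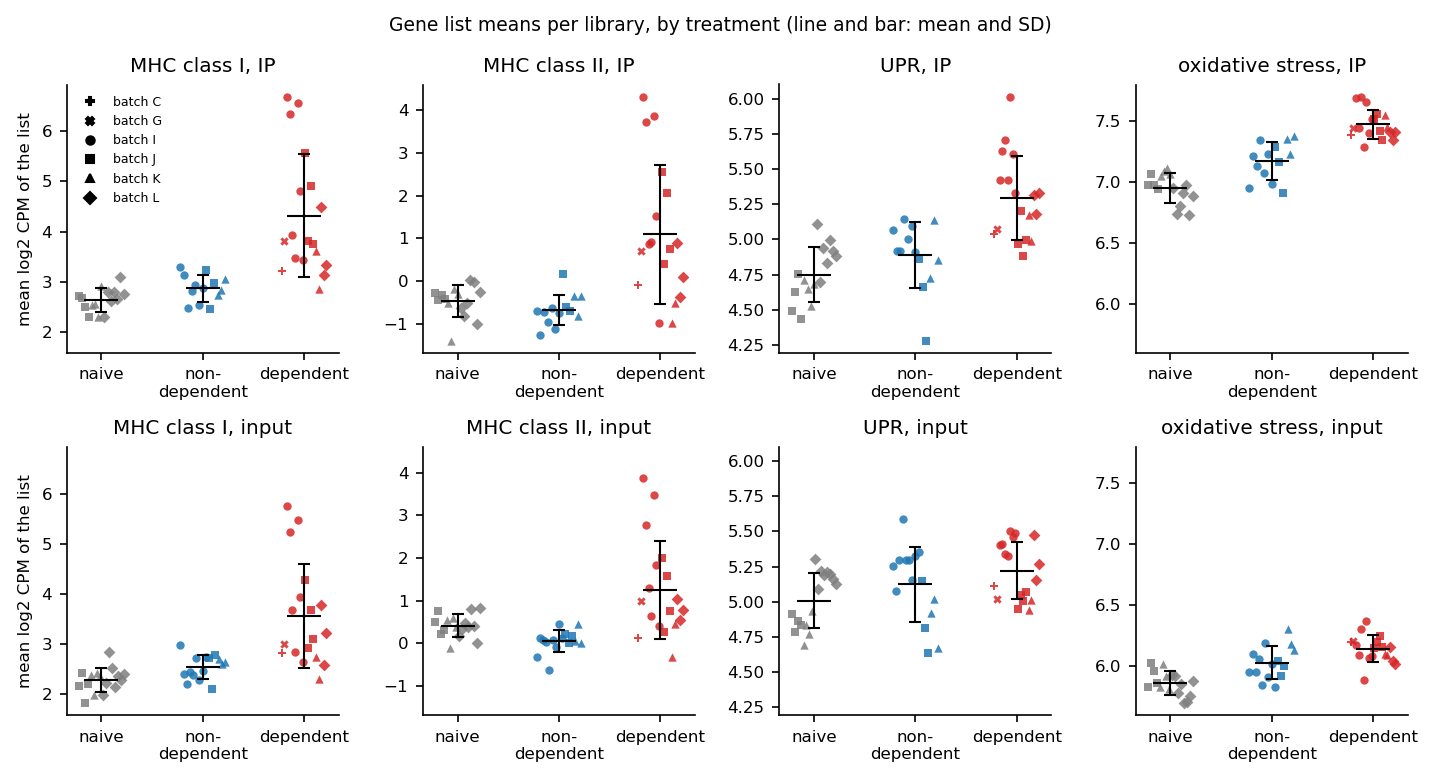
Mean log2 CPM of the tested members of gene lists in each library by treatment, in IP and input (points: libraries, lines and bars: mean and SD). In the MHC class I panels the dependent mice spread upward from the level of the other mice.

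The comparison of non-dependent with naive mice in IP asked what drinking without CIE does. In edgeR 88 genes differed, and no MHC, interferon or A1-like list was called higher. Fabp7 fell from 470 ± 133 CPM in 15 naive to 206 ± 67.6 CPM in 13 non-dependent libraries (log2 fold change -1.12 ± 0.15, adjusted p = 3.65e-05), and Gabbr2 from 248 ± 52.9 to 140 ± 17.2 CPM (-0.78 ± 0.13, adjusted p = 0.000855). Gabra2, a GABA-A receptor subunit, rose from 103 ± 27.01 to 157 ± 32.3 CPM (0.71 ± 0.14, adjusted p = 0.00594). It was less abundant in IP than in input (197 CPM in naive input), where its log2 fold change was 0.39. A share of RNA from other cells in its rise was not tested. Of 16 circadian clock genes, 3 rose and 13 did not pass (7 higher and 1 lower adjusted over the list alone, median 0.13, adjusted p = 0.497 with an estimated correlation), among them Per3 (0.72 ± 0.14). Of the 9 MHC class II genes none passed (0 adjusted over the list alone, median -1.24, adjusted p = 0.755 with an estimated correlation), and none of the 76 cytosolic ribosomal protein genes did (median -0.10, adjusted p = 0.787 with an estimated correlation). Hba-a2, an alpha-globin gene on chromosome 11 (ENSMUSG00000069917) with a near-identical neighbour, Hba-a1, had 16.5 ± 9.601 CPM in naive and 0.142 ± 0.120 CPM in non-dependent libraries (log2 fold change -6.19 ± 0.65, adjusted p = 8.22e-08). Gfap had a log2 fold change of 0.75 ± 0.20 (adjusted p = 0.0704).

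Other genes with the smallest adjusted p were Ocel1 (0.87 ± 0.15), Fam32a (0.64 ± 0.12) and the actin-severing gene Gsn (0.56 ± 0.11), which rose, and Gadd45gip1 (-1.05 ± 0.19), Btg3 (-1.17 ± 0.20) and the tetraspanin gene Tspan9 (-0.59 ± 0.10), which fell. Ocel1, Fam32a and Gadd45gip1 lie on chromosome 8, as do the called genes Fgl1 (-6.43), Ces1d (4.01) and Trim61 (5.93), which had low counts. Sfrp1 (1.11), Tox3 (0.83), Lsm4 (-0.42), Mpv17l2 (-0.41) and Adgrg1 (-0.53) lie there too. Chromosome 8 held the most called genes of any chromosome, and whether it held more than its share of tested genes was not tested. Many called genes lie on other chromosomes. For the called genes a strain variant shared by non-naive mice cannot be told apart from drinking. Of the 88 genes 48 were higher and 40 lower. Of the lists, 3 were called higher and 7 lower, and 0 kept the call with an estimated correlation in camera (fry called 1). Within batches J and K (3 against 4 mice in each) Fabp7 differed by -1.03 and -1.15, Gabbr2 by -0.86 and -0.75, Gabra2 by 0.87 and 0.72, Per3 by 0.77 and 0.68, the clock list by 0.22 and 0.34, and the MHC class II list by -0.02 and 0.11. Other immune lists were higher in both batches, MHC class I by 0.34 and 0.30, the lymphocyte, monocyte and border macrophage markers by 0.60 and 0.60, the interferon-inducible GTPases by 0.29 and 0.53 and the A1-like list by 0.49 and 0.37. Their medians in the fit over 4 batches were -0.23, 0.25, -0.35 and -0.06. In batches J and K alone 15 genes passed (the calls of Per3, Gsn, Btg3, Fam32a, Ocel1 and Tspan9 were lost, those of Per3 and Gsn also without a batch term) and without the naive female mouse J08 56, against 250 by DESeq2, 159 by limma voom, 155 without a batch term and 481 with no count filter.

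**Figure D4:**
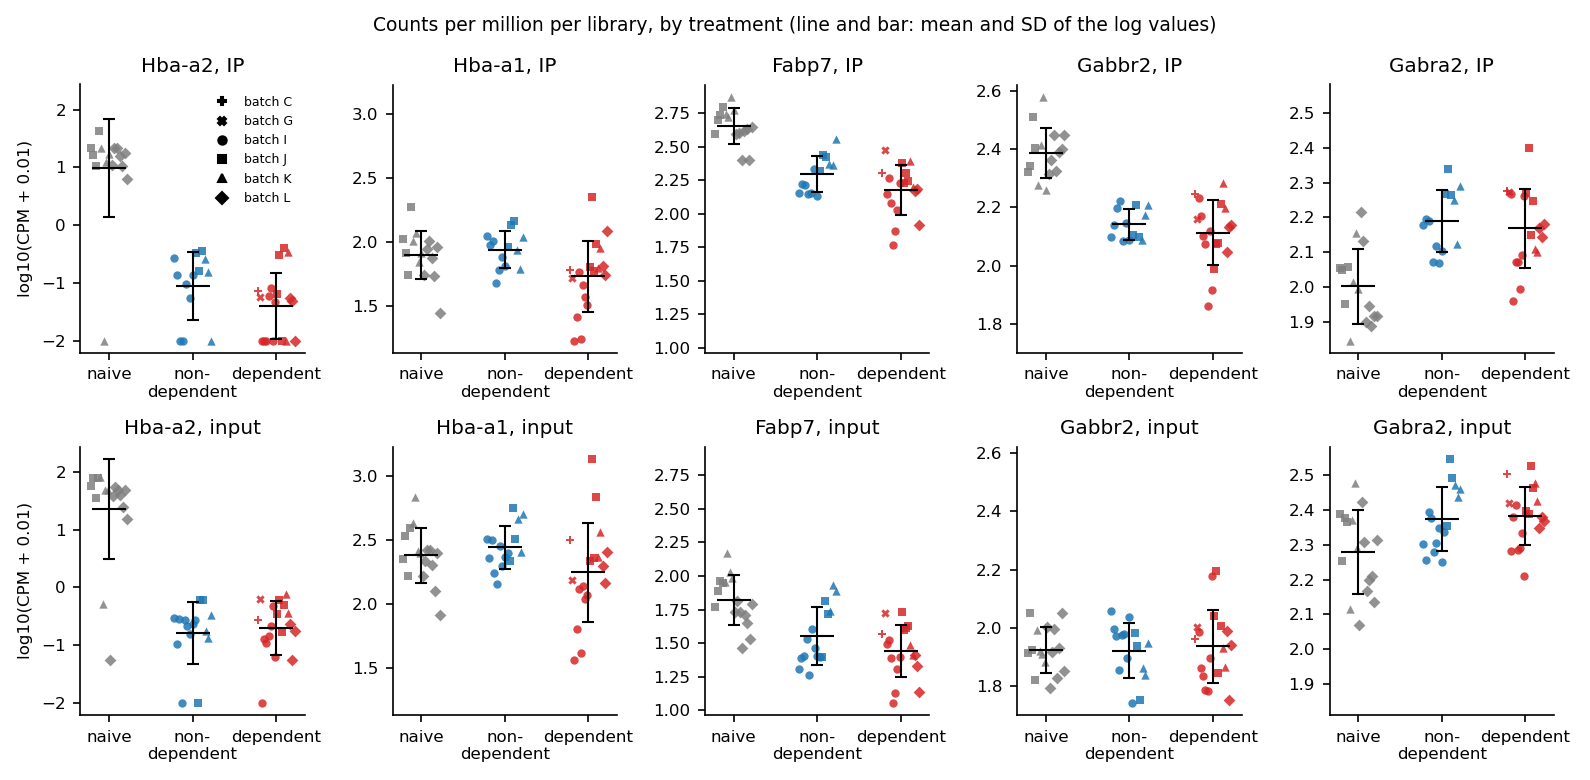
CPM per library on a log axis by treatment for genes that set naive mice apart from the other mice (points: libraries, lines and bars: mean and SD of the log values). Hba-a2 lies near 0 in all dependent and non-dependent libraries.

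In the input, the comparison of dependent with non-dependent mice asked whether the whole tissue shows the same. Antigen presentation and interferon genes were higher in dependent mice, while the folding and oxidative stress lists had few or no members past the threshold. Cd74 rose from 1.52 ± 0.552 CPM in 15 non-dependent to 47.4 ± 82.3 CPM in 16 dependent libraries (log2 fold change 4.70 ± 0.65, adjusted p = 0.000114). Psmb8 had 4.44 ± 1.63 and 15.6 ± 15.1 CPM (1.90 ± 0.29, adjusted p = 0.000227), and C4b 14.7 ± 4.29 and 35.0 ± 26.9 CPM (1.26 ± 0.19, adjusted p = 0.000234). Rgs4 fell from 215 ± 66.8 to 150 ± 27.9 CPM (-0.52 ± 0.10, adjusted p = 0.00691).

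Of 16 MHC class I and antigen processing genes, 12 rose and 4 did not pass (16 adjusted over the list alone, median 1.47), with the peptide transporter gene Tap1 at 2.44 ± 0.41. Of 9 MHC class II genes, 4 rose (7 adjusted over the list alone, median 1.71), with H2-Aa at 4.15 ± 0.62 and H2-Ab1 at 4.10 ± 0.61. Of 34 type I interferon response genes, 8 rose (23 adjusted over the list alone, median 0.89), with Bst2 at 2.17 ± 0.33, and of 14 interferon-inducible GTPases and interferon gamma response genes 6 rose (12 adjusted over the list alone, median 1.80). No member of these 4 lists fell, and they kept their call with an estimated correlation. Of 20 unfolded protein and integrated stress response genes none passed (0 adjusted over the list alone, median 0.08, adjusted p = 0.219 with an estimated correlation), and of 20 oxidative stress response genes 1 rose (2 adjusted over the list alone, median 0.00, adjusted p = 0.341 with an estimated correlation). Of 18 microglia markers 1 rose and 1 fell (median 0.13, list not called), and of 22 astrocyte markers 1 rose (4 adjusted over the list alone, median 0.08, adjusted p = 0.341 with an estimated correlation).

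In total 70 of 19691 tested genes differed, 61 higher and 9 lower, among them Ptgds, a prostaglandin D synthase gene (0.84 ± 0.13, call lost without a batch term), and Timmdc1, an assembly factor gene of respiratory complex I (77.3 ± 77.1 and 12.6 ± 15.4 CPM, -3.03 ± 0.61, adjusted p = 0.00985, call lost with limma voom). Of the lists, 20 were called higher and 2 lower, and 9 kept the call with an estimated correlation. Within batches I, J and K (7 against 9, 4 against 3 and 2 against 3 mice) the MHC class I list differed by 1.71, 0.96 and -0.13, the MHC class II list by 2.30, 1.13 and -0.11, and the interferon list by 0.94, 0.67 and 0.19. C4b differed by 1.39, 0.78 and 0.98, Rgs4 by -0.47, -0.55 and -0.53, and the microglia markers by 0.10, 0.17 and -0.24. In batches J and K alone edgeR called 0 genes (844 at an unadjusted p under 0.05), DESeq2 called 112 in the 4 batches, and 41 passed without the dependent male mouse I11. With a composition covariate 36 passed (31 higher and 5 lower), without a batch term 28, with only the mice that have an IP library 46 and with no count filter 119.

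In the input of dependent against naive mice, Gstm1, Etnppl, Vim and Gfap were among the higher genes and Rgs4 among the lower, while no called list kept its call with an estimated correlation in camera (fry called 14). Gstm1 rose from 523 ± 62.4 CPM in 16 naive to 879 ± 127 CPM in 16 dependent libraries (log2 fold change 0.73 ± 0.10, adjusted p = 4.34e-06). Etnppl, a phosphoethanolamine-degrading enzyme of astrocytes, rose from 9.01 ± 5.34 to 26.9 ± 13.9 CPM (1.43 ± 0.21, adjusted p = 3.08e-05). Rgs4 fell from 288 ± 52.5 to 150 ± 27.9 CPM (-0.91 ± 0.12, adjusted p = 1.93e-06). Also higher were Slc2a1, the glucose transporter GLUT1 (0.63 ± 0.08), the insulin-degrading enzyme gene Ide (0.69 ± 0.09), the Wnt antagonist gene Sfrp1 (1.15 ± 0.18), Mt1 (0.90 ± 0.14), Vim (0.87 ± 0.13) and Gfap (34.5 ± 17.7 and 102 ± 70.3 CPM, 1.03 ± 0.19). Also lower were Hba-a2 (-7.29 ± 0.61, call lost with limma voom), Fabp7 (-1.18 ± 0.18), Btg3 (-1.09 ± 0.16) and Tspan9 (-0.58 ± 0.10). Ide, Hba-a2, Btg3 and Tspan9 moved the same way in the input of non-dependent against naive mice. For such genes a strain variant shared by the non-naive mice cannot be told apart from ethanol.

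Of 16 MHC class I and antigen processing genes, 7 rose (15 adjusted over the list alone, median 1.20, adjusted p = 0.0516 with an estimated correlation), and of 34 type I interferon response genes 7 rose (9 adjusted over the list alone, median 0.57, adjusted p = 0.12 with an estimated correlation). Of 20 oxidative stress response genes 5 rose (7 adjusted over the list alone, median 0.13, adjusted p = 0.0516 with an estimated correlation), and of 16 clock genes 5 rose (11 higher and 1 lower adjusted over the list alone, median 0.30, adjusted p = 0.0516 with an estimated correlation). Of 11 pan-reactive astrocyte genes 2 rose, Vim and Gfap (3 adjusted over the list alone, median 0.42, adjusted p = 0.0516 with an estimated correlation). Of 22 astrocyte markers 2 rose (3 adjusted over the list alone, median 0.06, adjusted p = 0.344 with an estimated correlation). Of 13 oligodendrocyte markers 1 fell (4 adjusted over the list alone, median -0.19, adjusted p = 0.279 with an estimated correlation), and of 16 medium spiny neuron markers none passed (2 lower adjusted over the list alone, median -0.22, adjusted p = 0.325 with an estimated correlation). In total 469 genes differed, 279 higher and 190 lower, and 15 lists were called higher and 5 lower, of which 0 kept the call with an estimated correlation in camera (fry called 14). Within batches J, K and L (4 against 4, 2 against 4 and 3 against 8 mice) Gstm1 differed by 0.70, 0.75 and 0.71, Etnppl by 1.42, 1.88 and 1.04, and Rgs4 by -0.76, -1.11 and -0.97. The MHC class I list differed by 1.34, 0.23 and 0.85, and the clock list by 0.27, 0.48 and 0.12. In batches J and K alone 17 genes passed and Vim, Gfap, Rgs4, Mt1, Sfrp1, Fabp7, Btg3 and Tspan9 lost their call, as Mt1 and Tspan9 did without a batch term. With a composition covariate 227 genes were higher and 224 lower, and 10 lists higher and 7 lower, while without the naive female mouse J08 312 genes passed and without the dependent female mouse L25 262, and DESeq2 called 707.

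In the input of non-dependent against naive mice, 24 genes differed in edgeR. Per2, a repressor of the clock, rose from 10.3 ± 4.38 CPM in 16 naive to 19.7 ± 6.32 CPM in 15 non-dependent libraries (log2 fold change 1.12 ± 0.18, adjusted p = 0.00055). Ide (0.60 ± 0.10), Gstm1 (0.56 ± 0.11) and Fam32a (0.57 ± 0.09) also rose. Hba-a2 fell from 43.6 ± 24.8 to 0.236 ± 0.174 CPM (-7.35 ± 0.74, adjusted p = 6.67e-08, call lost with limma voom), and Gadd45gip1 (-0.90 ± 0.12), Tspan9 (-0.77 ± 0.11), Btg3 (-1.18 ± 0.17) and Tpd52l1 (-0.93 ± 0.16) fell as well. Of 16 clock genes, 2 rose (9 higher and 1 lower adjusted over the list alone, median 0.30, adjusted p = 0.143 with an estimated correlation). Of 20 immediate early genes none passed (2 lower adjusted over the list alone, median -0.34, adjusted p = 0.368 with an estimated correlation), and of 9 MHC class II genes none passed (2 lower adjusted over the list alone, median -1.07, adjusted p = 0.368 with an estimated correlation). Of 7 blood cell markers 1 fell, which was Hba-a2. Their median was 0.29, their mean -1.70 and the camera direction down (adjusted p = 0.374 with an estimated correlation). Of the 24 genes 12 were higher and 12 lower, and 3 lists were called higher and 9 lower, of which 0 kept the call with an estimated correlation in camera (fry called 1). Within batches J and K (3 against 4 mice in each) Per2 differed by 1.45 and 0.96, Ide by 0.79 and 0.67, and Hba-a2 by -7.28 and -5.92. The clock list differed by 0.34 and 0.36, the immediate early genes by -0.01 and -0.52, and the MHC class II list by -0.36 and -0.20. In batches J and K alone 8 genes passed (Fam32a, Gstm1, Btg3 and Tpd52l1 lost their call, and Tspan9 did without a batch term), against 60 by DESeq2, 61 by limma voom, 51 without a batch term and 77 with no count filter.

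The paired fit asked whether the treatment differences were larger on astrocyte ribosomes than in the whole tissue of the same mice. Between dependent and non-dependent mice the IP gained more than the input for folding, interferon and antigen presentation genes. Calr went from 198 ± 45.7 to 387 ± 151 CPM in IP and from 204 ± 62.7 to 229 ± 76.6 CPM in input, a difference of log2 ratios of 0.74 ± 0.11 (adjusted p = 0.000184). Xaf1 had 8.33 ± 2.65 and 34.0 ± 31.6 CPM in IP and 11.2 ± 4.50 and 18.3 ± 11.5 CPM in input (1.26 ± 0.18, adjusted p = 0.000139). The same direction held for Oasl2, an interferon-induced gene (2.01 ± 0.31), Serping1 (1.48 ± 0.25), H2-T23 (1.27 ± 0.21), Manf (0.63 ± 0.11) and Cebpb (0.93 ± 0.17). Of 20 unfolded protein and integrated stress response genes, 5 had a larger difference in IP (11 adjusted over the list alone, median 0.29). Of 35 type I interferon response genes 4 did (9 adjusted over the list alone, median 0.43), of 16 MHC class I genes 2 (8 adjusted over the list alone, median 0.32) and of 20 oxidative stress response genes none (6 adjusted over the list alone, median 0.18), and these 4 lists kept their call with an estimated correlation. None of 18 microglia markers passed (0 adjusted over the list alone, median 0.24, adjusted p = 0.22 with an estimated correlation). In total edgeR called 20 of 21659 tested genes, all with a larger difference in IP, 12 with the added dispersion estimate and 0 without the mouse block (1228 at an unadjusted p under 0.05). DESeq2 called 47, of which 25 had a higher and 22 a lower IP-over-input ratio in dependent mice.

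Between dependent and naive mice 77 genes differed, 35 with a higher and 42 with a lower IP-over-input ratio in dependent mice (12 without the mouse block, 143 by DESeq2). Cebpb (1.08 ± 0.19), Ddit4l, a repressor of mTOR signalling (1.11 ± 0.17), the immunoproteasome gene Psmb9 (1.36 ± 0.23) and Gclc (0.60 ± 0.11) had higher ratios. Crym, a thyroid hormone binding protein gene, went from 3327 ± 761 to 1354 ± 474 CPM in IP and from 623 ± 139 to 455 ± 93.8 CPM in input (-0.74 ± 0.12, adjusted p = 0.000781), and Fabp5 (-0.75 ± 0.12), the tubulin gene Tuba1a (-0.44 ± 0.07) and the PACAP receptor gene Adcyap1r1 (-0.59 ± 0.10) also had lower ratios. Of 20 unfolded protein and integrated stress response genes 3 had a higher ratio (7 adjusted over the list alone, median 0.24), and of 18 microglia markers 1 did (7 adjusted over the list alone, median 0.31, adjusted p = 0.0479 with an estimated correlation). None of 22 astrocyte markers passed (6 lower adjusted over the list alone, median -0.15, adjusted p = 0.0501 with an estimated correlation). Between non-dependent and naive mice edgeR called 0 genes (1199 at an unadjusted p under 0.05) and DESeq2 11.

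Sex-linked genes were the ones that separated male from female mice. Ddx3y, a Y-linked RNA helicase gene, had 32.4 to 75.4 CPM in the 43 libraries of males and at most 0.0918 CPM in the 52 of females. Uty, Kdm5d and Eif2s3y were at or above 2.77, 2.29 and 7.44 CPM in males and at or below 0.134, 0.0560 and 0.803 CPM in females. Xist, the RNA that silences an X chromosome, had a median of 8.61 CPM in females (from 0.952) and 0 in males (up to 1.25). In each fraction 10 genes passed, 5 higher and 5 lower in males. The lower ones included the X-linked Ddx3x (IP -0.49 ± 0.05, input -0.41 ± 0.04) and Eif2s3x (IP -0.55 ± 0.08, input -0.55 ± 0.06), Pbdc1 in IP (-0.36 ± 0.07) and Kdm6a in input (-0.51 ± 0.08). Without a batch term Pbdc1 in IP and Ddx3x in input lost their call. Of the lists, camera called 1 higher and 7 lower in males in IP, and 1 higher and 5 lower in input. In both fractions 0 kept the call with an estimated correlation.

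The treatment differences themselves were not shown to differ between the sexes. For dependent against naive mice edgeR called 219 genes in females and 169 in males in IP, and 0 genes for the difference between the sexes (627 at an unadjusted p under 0.05, DESeq2 14, limma voom 0). For dependent against non-dependent mice it called 79 in females and 13 in males, and 0 for the difference (668 at an unadjusted p under 0.05, DESeq2 15, limma voom 0). In the input it called 148 genes in females and 19 in males for dependent against naive mice, and 24 and 0 for dependent against non-dependent mice (967 in males at an unadjusted p under 0.05, DESeq2 4, limma voom 1). The difference between the sexes had 0 calls in both input comparisons (540 and 607 at an unadjusted p under 0.05, with 0 by DESeq2 and by limma voom). Of the lists, camera called 3 lower for the difference between the sexes in IP for dependent against naive mice, 5 higher and 3 lower in IP and 3 higher and 4 lower in input for dependent against non-dependent mice. Of these, 0 kept the call with an estimated correlation.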

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

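The tests of carried-over RNA and of batch below were chosen after the values had been seen, and the test by chromosome and the counts of other splits before.

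Of 96 sets of values (8 measures in 12 groups), 3 held a library that stood apart from the rest of its group by Dixon's gap test, which chance gives in about 1 of 20 sets. The IP library of the non-dependent male I06 had a composition score of 3.95, with the next of the 5 libraries at 3.46 and the lowest at 3.34. The input library of the naive female L27 had a mean log2 CPM of 2.84 over the MHC class I list, with the next of 8 at 2.39 and the lowest at 2.13. The IP library of the naive male J02 had a mean log2 CPM of 2.22 over the type I interferon list, with the next of 7 at 1.60 and the lowest at 1.18.

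Treatment differences differed between IP and input for 77 genes (dependent against naive mice) and 20 genes (dependent against non-dependent mice), by the paired test of that difference. When the treatments of the mice were permuted within batch and sex, 1 of 21 splits, the real one, gave 77 or more genes, and the highest of the others gave 0. For dependent against non-dependent mice 1 of 21 splits gave 20 or more, and the highest of the others gave 1. In both, no other split reached the real count, but 21 splits are too few to exclude chance firmly.

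A pattern to follow up is the higher level of MHC and interferon genes on the astrocyte ribosomes of dependent mice, with 48 called members of 4 lists between dependent and non-dependent mice. Of 18 microglia markers 4 rose in IP too (list adjusted p = 0.328 with an estimated correlation), and for their IP-over-input ratio none passed against non-dependent mice (median 0.24, adjusted p = 0.22 with an estimated correlation) and 1 against naive mice (median 0.31, adjusted p = 0.0479 with an estimated correlation). In 18 dependent mice the median log2 ratio of IP to input was 1.19 (SD 0.736) for the 48 called genes and -0.98 (SD 0.306) for 18 microglia markers. The difference was 2.17, although the 5 called MHC class II genes lay at 0.34 (for C1qb, an abundant microglia gene, 71.5 and 190.2 CPM on average in IP and input of 46 mice). The 48 genes were chosen by their rise in the same IP libraries, which raises their ratio. The interferon list, not chosen by that rise, was also enriched in IP over all treatments, dependent mice included (median 1.01). The 48 genes as a set were thus not depleted in IP as the microglia markers were. Since their choice favours a high ratio, that cannot decide how far RNA of microglia carried into the IP was their source. The dependent mice with the highest MHC class I means were I02, I11, I05 and J05. Their microglia marker means in IP (5.48, 4.15, 4.36 and 4.86 log2 CPM) lay above those of the non-dependent mice of their batches. The ratio cannot tell where the rise of these genes came from, and it was not computed for markers of other leukocytes. Over all treatments, 9 of 10 lymphocyte, monocyte and border macrophage markers were lower in IP than in input and 0 higher (median -1.08, adjusted p = 0.106 with an estimated correlation). Between dependent and naive mice 1 of 7 such markers rose in IP (median 0.60, adjusted p = 0.614 with an estimated correlation). A strain variant at the H2 locus that acts on genes of that locus is argued against for the 66.7% of called members (32 of 48) outside chromosome 17. For the 16 on chromosome 17 it stays open, and the share depends on the pooling of interferon lists with H2 genes. Batch is argued against as the whole cause. The mean over the tested members differed by 2.08 ± 0.611 (SE) within batch I (7 against 7 mice) and by 1.44 ± 0.430 within batch J (4 against 3). Within batch K it differed by only 0.0441 ± 0.192 (2 against 3). Microglial RNA as a source of the pattern and a response of the astrocytes themselves to dependence, which was not tested, stay open. So does why dependent mice differ so widely among themselves.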

How the results depend on the processing

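These limits concern counts of called genes and lists, and the tests named here were planned except the dispersion estimate of the paired fits, which was added after seeing the data. Of 133 alternatives for a count of genes, 93 stayed within 1.5 times the reported count, and so did 49 of 96 for a count of genes within 1 sex and 24 of 38 for a count of lists. Of 1237 alternatives for a named gene, 1150 kept direction and call, 85 kept the direction and lost the call, 2 gained the call and 0 turned direction. Of 662 alternatives for a called list, 446 kept direction and call, 213 lost the call and 3 turned direction. The alternative for shallow libraries removed nothing, since the lowest total was 0.686 of the median in IP and 0.741 in input, and was not run. At the simulated dispersion of 0.05, without batch or mouse effects, 1.5-fold changes were recovered in 59.7% of cases for dependent against naive mice in IP. For dependent against non-dependent mice the share was 68.7%. Genes that vary more among mice would be recovered less often.

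With batches J and K alone, which leaves fewer samples and takes out batches I and L, edgeR called 235 genes for dependent against naive mice in IP and 17 in input, 0 for dependent against non-dependent mice in IP (1720 at an unadjusted p under 0.05, with DESeq2 at 492 and limma voom at 229 in the 4 batches) and 0 in input (844 at an unadjusted p under 0.05), 15 and 8 for non-dependent against naive mice, and 6 for the sexes in IP. The MHC and interferon difference in IP was 2.08 in batch I, 1.44 in J and 0.0441 in K, and in that subset the fitted log2 fold change between dependent and non-dependent mice in IP was 0.31 for Calr (0.83 in all batches), 1.68 for Igtp (3.14) and 1.31 for Cebpb (1.49). In that subset 14 lists were called for dependent against non-dependent mice in input. Directions turned there for the MHC class II list between non-dependent and naive mice in IP (adjusted p = 0.99), the blood cell markers between dependent and non-dependent mice in input (adjusted p = 0.655) and the NF-kB list between non-dependent and naive mice in input (adjusted p = 0.816).

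With no count filter, which tests more genes, the counts were 1447 (dependent against naive), 684 (dependent against non-dependent), 481 (non-dependent against naive) and 96 (sexes) in IP, and 119, 77 and 25 for the last 3 in input. The sex differences of the treatment effects then had 38 (against naive) and 40 (against non-dependent) in IP and 1 (against naive) in input. Without a batch term and with batches C and G added, dependent against non-dependent mice gave 92 in IP and 28 in input. Non-dependent against naive mice gave 155 and 51. The composition covariate gave 36 for dependent against non-dependent mice in input, and only mice with an IP library gave 46.

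DESeq2 called 492 and 112 genes for dependent against non-dependent mice in IP and input, 250 and 60 for non-dependent against naive mice, 707 for dependent against naive mice in input, 21 for the sexes in IP, and 14 and 15 for the sex difference of the 2 dependent comparisons in IP. Limma voom called 159 and 61 for non-dependent against naive mice in IP and input. In the paired fits by treatment DESeq2 called 143 (dependent against naive), 47 (dependent against non-dependent) and 11 (non-dependent against naive). With the added dispersion estimate they had 12 for dependent against non-dependent and 1 for non-dependent against naive mice. Without the replicate block of the mouse they had 12 for dependent against naive and 0 for dependent against non-dependent mice (1228 at an unadjusted p under 0.05, edgeR). The block changed no other count by more than 1.5 times: IP against input had 16939 genes without it.

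For lists, camera with an estimated correlation called 5 for dependent against naive mice in IP and 0 in input, 9 for dependent against non-dependent mice in input, 0 for non-dependent against naive mice in both fractions, and 8 and 0 in the paired fits for dependent and non-dependent mice and for non-dependent and naive mice. Fry called 11 for dependent against non-dependent mice in input, 1 for non-dependent against naive mice in each fraction, 40 for IP against input, and 10 and 0 in those paired fits. The cause was not tested for any of these moves.

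Leaving out 1 library at a time, IP counts ran from 664 to 1031 for dependent against naive, 230 to 359 for dependent against non-dependent and 56 to 123 for non-dependent against naive mice. Input counts ran from 262 to 535, 41 to 84 and 20 to 33. Counts moved over 1.5 times without the naive female J08 (56 in IP for non-dependent against naive, 312 in input for dependent against naive mice), the dependent female L25 (262 in input for dependent against naive mice) and the dependent male I11 (41 in input for dependent against non-dependent mice). The sex difference of dependent against non-dependent mice in IP had 0 calls in edgeR without each of the 5 male non-dependent libraries (668 at an unadjusted p under 0.05 with all, DESeq2 15).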

Other observations

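The tests of blood, of clock phase and of glucocorticoid targets below, and the comparison of neighbouring genes with dependent against non-dependent mice, were chosen after the values had been seen, and those of the paralog, of neighbouring genes and of other splits before.

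Other gene groups moved with dependence. Between dependent and non-dependent mice, of 15 glucocorticoid targets 3 rose in IP (10 adjusted over the list alone, median 0.37) and 1 in input (8 adjusted over the list alone, median 0.33), and of the NF-kB targets, cytokines and chemokines 7 of 29 rose in IP (8 higher and 1 lower adjusted over the list alone, median 0.55) and 4 of 30 in input (8 adjusted over the list alone, median 0.31). Both lists kept their call with an estimated correlation in both fractions (adjusted p = 0.0147 and 0.0057, and 0.00535 and 0.0112). Of 20 immediate early genes, 3 rose in IP (5 adjusted over the list alone, median 0.34, adjusted p = 0.0717 with an estimated correlation) and 1 in input (8 adjusted over the list alone, median 0.31, adjusted p = 0.0588 with an estimated correlation). Within batches I, J and K the glucocorticoid targets differed by 0.38, 0.31 and 0.58 in IP.

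Against naive mice, ependymal and choroid plexus markers had positive medians in both dependent and non-dependent mice. Of 10 such markers 1 rose in dependent mice in IP (8 adjusted over the list alone, median 0.98, adjusted p = 0.0572 with an estimated correlation) and 1 in input (7 adjusted over the list alone, median 0.93, adjusted p = 0.0622 with an estimated correlation). In non-dependent mice none passed in either fraction (0 and 1 adjusted over the list alone, medians 0.68 and 0.57, adjusted p = 0.587 and 0.374 with an estimated correlation). Within batches J and K the list was higher in non-dependent than in naive mice by 1.65 and 0.88 in IP and by 1.57 and 0.67 in input. Between dependent and naive mice none of the 13 mitochondrially encoded transcripts passed in IP (0 adjusted over the list alone, median -0.21, adjusted p = 0.309 with an estimated correlation). Between non-dependent and naive mice none passed in IP either (median -0.27, adjusted p = 0.665 with an estimated correlation). Within batches J and K that list differed by -0.08 and -0.44 between non-dependent and naive mice. Genes of alcohol and aldehyde metabolism were enriched on astrocyte ribosomes, with 10 of 13 higher and 3 lower in IP than in input (10 and 3 adjusted over the list alone, median 2.17, adjusted p = 0.00589 with an estimated correlation).

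The alpha-globin gene Hba-a2 was near 0 outside naive mice, at most 0.384 CPM in dependent and 0.352 CPM in non-dependent IP libraries, and among naive mice both libraries of the male K14 (0 CPM in IP and 0.506 CPM in input) and the input library of the male L23 (0.0449 CPM) were also near 0. More blood in naive samples is argued against, since the other blood markers had a median log2 fold change of 0.317 between non-dependent and naive mice in input. Reads moved to the paralog Hba-a1 stay open: it had a log2 fold change of 0.659, under the bound of 1 set beforehand, but that bound was too high, since Hba-a2 held 43.6 CPM and Hba-a1 269.9 CPM in naive input. A variant of the mixed strain background shared by non-naive mice stays open: 23 of the 97 genes called between non-dependent and naive mice in either fraction have another within 1 Mb, against a median of 12 in 10000 draws of as many tested genes, and 131 draws gave as many. An excess also arose between dependent and non-dependent mice, which would share such a variant: 151 of 332 called genes have a neighbour (median draw 115, 5 draws as many). There, 16 of the called MHC and interferon genes lie on chromosome 17. That comparison therefore cannot tell whether the first excess comes from a variant. A count within 1 Mb also does not measure how called genes spread over whole chromosomes. Between non-dependent and naive mice chromosome 8 held the most of them. Between dependent and naive mice so many genes were called that most drawn genes have a neighbour (844 of 1187, median draw 844).

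Some clock genes stood higher than in naive mice, 3 of 16 in IP and 2 of 16 in input for non-dependent and 4 of 16 and 5 of 16 for dependent mice, and the list did not keep its call with an estimated correlation (adjusted p = 0.497, 0.143, 0.0854 and 0.0516). A shift of clock phase stays open, since the activators Arntl, Clock and Npas2 had a median log2 fold change of -0.0566 in input between non-dependent and naive mice (from -0.46 to 0.10) while 9 repressors and output genes had a median of 0.46 (from -0.15 to 1.12). Between dependent and naive mice in input the medians were 0.0167 (from -0.38 to 0.18) and 0.36, so the activators did not fall there as a group. A difference in glucocorticoid level stays open too, since 14 targets outside the clock had a median of -0.0467 (SD 0.303) in that non-dependent comparison in input, with members in both directions. Between dependent and naive mice their median was 0.247 (SD 0.366) in input and 0.451 (SD 0.395) in IP. Hours of tissue collection were not given in the sources used here, so these cannot be told apart from an effect of the treatment.

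Timmdc1, which fell between non-dependent and dependent mice in input, was singled out after its values were seen, because it was high in one library of a mouse and not in the other. In the naive female J01 it had 12.6 CPM in IP and 227 CPM in input, and in the naive male J02 116 and 9.72 CPM. Input libraries ranged from 5.96 to 69.8 CPM in dependent and from 7.42 to 241 CPM in non-dependent mice.

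Other splits of the mice were drawn with the treatments permuted within batch and sex, or the sexes within batch and treatment. In IP, 1 of 80 splits, the real one, gave as many genes for each treatment comparison: 933 for dependent against naive mice (highest of the others 417), 308 for dependent against non-dependent mice (61) and 88 for non-dependent against naive mice (10). In input 1 of 80 gave the 469 genes for dependent against naive mice (25), 2 of 80 the 70 genes for dependent against non-dependent mice (219) and 2 of 80 the 24 genes for non-dependent against naive mice (61). No other split reached the real count in IP, or for dependent against naive mice in input. For the other input counts another split gave more genes than the real one, so chance cannot be excluded for them. What set the splits with 417, 219 and 61 genes apart was not tested. For IP against input, with the fractions of each mouse swapped at random, 1 of 21 splits gave 17078 or more genes (highest of the others 2). For the sexes 1 of 40 splits, the real one, gave 10 or more genes in IP (highest of the others 1). In input 2 of 40 did (62), so the splits alone do not exclude chance for that count, while Ddx3y and 3 other Y-linked genes set males and females apart in all 95 libraries. For the 4 sex differences of treatment effects the real count was 0 in edgeR, which 40 of 40 splits reach (highest of the others 1 and 0 in IP, 2 and 478 in input). What set the splits with 62 and 478 genes apart was not tested. For non-dependent against naive mice in the paired fit the real count was 0 in edgeR, which 21 of 21 splits reach (highest of the others 1, with 1199 genes at an unadjusted p under 0.05 and 11 by DESeq2).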
